A study of Homo sapiens with 2 samples.

How the data were processed

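RNA was sequenced from MiaPaCa cells, an established human pancreatic cancer cell line, in 2 libraries. The Scr control library came from cells that carried a plasmid with a scrambled hairpin. The MYB-silenced library came from cells that carried a short hairpin RNA plasmid against MYB. Per the labels' protocols, both were puromycin-selected stable pools, total RNA was extracted with a column kit and libraries followed standard Illumina procedures. Each group has 1 library, so no spread between replicates can be given and no test was run across genes. Any p-value quoted below is the authors' own and compares 2 libraries, not 2 conditions. The labels describe the Scr control cells as overexpressing MYB, although the protocols describe only the hairpin and the scrambled plasmids.

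The deposited table holds FPKM values of the 2 libraries (fragments scaled to transcript length and to the number of mapped fragments), made by the authors. CASAVA 1.8.2, TopHat, Bowtie, Cufflinks and the build hg19 are named per the submitters' processing notes, without their roles, parameters or annotation. Scaling between libraries, any correction for GC content and the strand setting are not given in the sources used here. Beside the FPKM values, the authors deposited a signed fold score (0 where a value is 0), a log2 ratio without a pseudocount, and an unadjusted p-value. The deposited log2 ratio lay within 0.001 of the log2 of the FPKM ratio for all 801 loci above 0 in both libraries. No adjusted p-value and no number of tested genes is given in the sources used here. The table lists 836 gene loci with 831 distinct gene names, all with a deposited p-value of 0.04995 or less, so genes that did not pass that p-value were not analysed here. Fold changes of the listed loci are therefore those of a selected set. No count and no library total is given, so sequencing depth is unknown and no counting interval or detection floor was computed. FPKM steps could not be turned into whole reads, because 1 value per gene and library is left after the authors' length and depth scaling.

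All ratios below were computed from the FPKM values as log2(MYB-silenced + 0.5) minus log2(Scr + 0.5), which understates the change of weakly expressed genes. Negative values mean lower in the MYB-silenced library. Loci with a mean of both libraries of at least 1 FPKM (797 loci) entered the counts of 2-fold differences (an absolute log2 ratio of at least 1) and the gene lists. A value of exactly 0 can be a failed estimate and is given only as listed at 0. Loci of several genes are kept under their joint name, and a locus counts for a list if any of its genes is a member. Loci on alternate haplotype contigs share reads with the main chromosome, so the values of both are uncertain.

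The following were fixed before the data were examined: the groups, 50 gene lists, the 2-fold and level rules, and the rule for named genes. That rule names MYB and its relatives and the 10 lowest and 10 highest protein-coding loci above 0 in both libraries. It also names up to 4 loci per list by the size of the ratio, the listed members of the list of reported MYB targets, and the 3 highest loci listed at 0 in each direction. For lists with at least 4 loci that pass the level filter, the median log2 ratio was placed among 10000 random lists of the same size, drawn from the listed loci and matched on mean FPKM in 20 bins. The percentile describes these libraries and is no p-value. On simulated data with 797 loci and lists of 12, it fell outside 2.5 to 97.5 for 3 of 100 unshifted lists. It did so for 71 of 100 lists shifted by -0.5 and for 73 of 100 lists shifted by -1 on the log2 scale. A recovery of at least 80 of 100 had been required beforehand at the larger shift, was missed, and was dropped as a requirement after this result. The misses came from lists with few lower loci: at the larger shift, 67 of 67 lists with at least 7 lower loci before the shift were found, and 6 of the 33 others. A percentile inside that range therefore does not exclude a shift. The share of lower loci was simulated with directions set by a covariate alone and lists drawn from its lower part. It fell outside the range for 37 of 100 lists matched on level and for 5 of 100 matched on the covariate. Its power was not simulated. The design had foreseen a table of all genes, so percentiles compare a list with other listed loci only.

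Coordinates are those of the table (hg19), with the start raised by 1. Among 745 single-gene loci, the gene length in a RefSeq table equalled end minus start for 41 and end minus start plus 1 for 7, so the printed start was taken to count from 0. GC content and length of transcripts are medians over a gene's GENCODE release 29 transcripts, matched by current or older symbol, and were found for 783 of the 836 loci (93.7%). No coordinates of that annotation were used.

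Alternatives planned in advance were pseudocounts of 0.1 and 1, no level filter, a mean of at least 5 FPKM, centring of the ratios, folds of 1.5 and 3, means in place of list medians, and stricter subsets of the authors' calls. Matching on GC content or length (10 bins), and leaving out loci at 0 with small RNA genes or loci on extra contigs, were added after seeing the data. A ratio that moved by more than 1.5-fold is described as moved, since no replicate spread exists. Scaling to a common sum and quantile normalization were not run, because the table holds only selected genes, and no library could be left out of groups of 1. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The values of some genes are not reported here.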

Results

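The transcriptomes of 1 Scr control library and 1 MYB-silenced library of MiaPaCa pancreatic cancer cells were compared, to find the genes whose expression differs between cells that express the transcription factor MYB and cells in which it is silenced. The authors' deposited table lists 836 loci, of which 516 (61.7%) were lower and 320 were higher in the MYB-silenced library. The listed loci had a median of 13.9 FPKM in the Scr control library and 11.2 FPKM in the MYB-silenced library. Without replicates no error can be attached to any value below, and sequencing depth is unknown.

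MYB itself (chromosome 6, 135502453 to 135540311, hg19) was at 981 FPKM in the Scr control library and at 0.554 FPKM in the MYB-silenced library. The silenced level was 0.0564% of the control level, a log2 ratio of -9.86, and the p-value in the authors' deposited table was 5e-05. The labels describe the control cells as overexpressing MYB, so this ratio cannot be read as the silencing of endogenous MYB alone. MYB had the highest FPKM of all listed loci in the Scr control library, above LDHA at 802 FPKM and S100A6 at 793 FPKM. Its relative MYBL1 (chromosome 8, 67474410 to 67525480) was at 17.2 FPKM in the control and 8.31 FPKM after silencing, a log2 ratio of -1.01. MYBL2 was not among the listed loci.

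Of the 797 loci with a mean of at least 1 FPKM, 497 were lower and 300 higher after silencing. At least 2-fold differences were found for 197 lower loci, 14 of them listed at 0 in the MYB-silenced library, and for 159 higher loci, 15 of them listed at 0 in the Scr control library. Centring subtracts the median ratio of the listed loci, -0.80, which is that of genes selected for change. It turned this split into 31 lower and 300 higher loci. In the plot of FPKM values, MYB lies far from every other locus above 0 in both libraries.

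**Figure D1:**
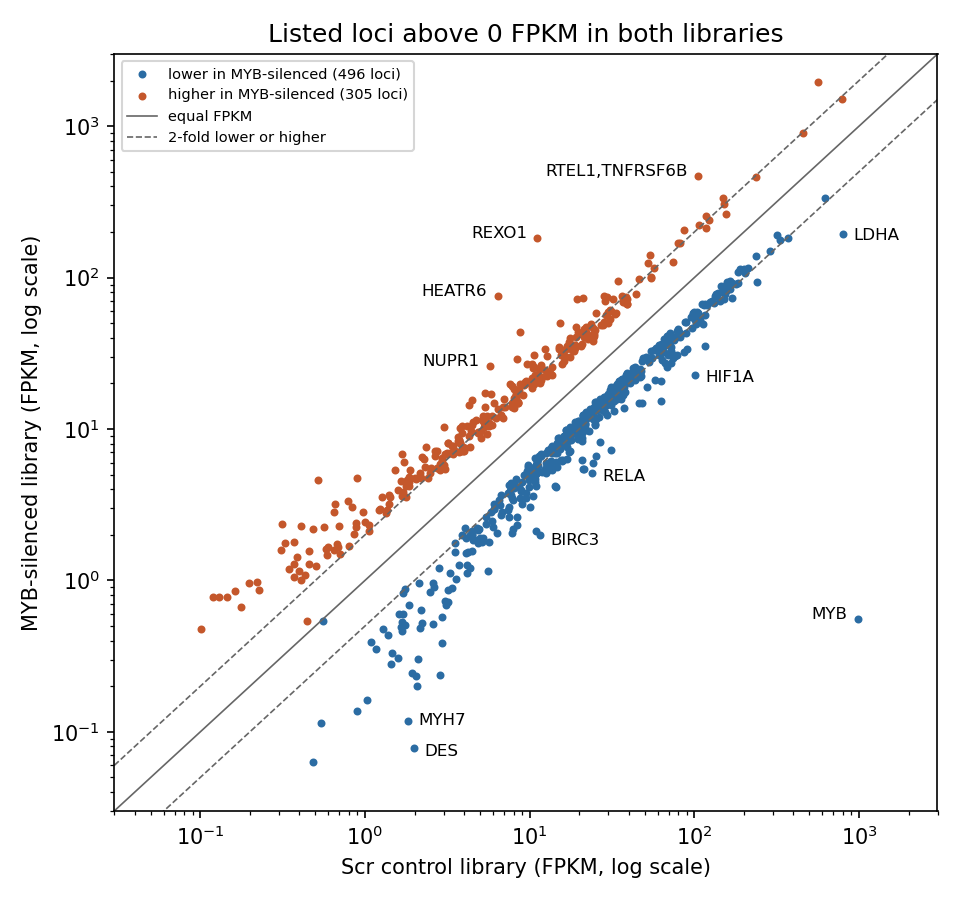
FPKM of the 801 listed loci above 0 in both libraries, Scr control on the horizontal and MYB-silenced on the vertical log axis; each point is 1 locus, the solid line marks equal values and the dashed lines 2-fold differences. MYB lies at 981 and 0.554 FPKM, and few listed loci lie near equality because the table holds selected genes.

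Among protein-coding loci above 0 in both libraries, the lowest ratios after that of MYB belonged to genes of several pathways. BIRC3, an inhibitor of apoptosis, was at 11.6 FPKM in the control and 1.99 FPKM after silencing (log2 ratio -2.28). HIF1A, the oxygen-regulated subunit of the hypoxia-inducible factor, was at 101 and 22.6 FPKM (log2 ratio -2.13), and its locus overlaps that of the antisense gene HIF1A-AS2, and without strand the reads of the pair cannot be told apart. RELA, the p65 subunit of NF-kB, was at 23.8 and 5.14 FPKM (log2 ratio -2.11). The Wnt antagonist DKK1 was at 10.9 and 2.11 FPKM (log2 ratio -2.13). Lactate dehydrogenase A, LDHA, was at 802 and 194 FPKM (log2 ratio -2.04), and the caveolar coat protein CAV1 was at 24.1 and 5.95 FPKM (log2 ratio -1.93). The remaining 3 were weakly expressed. Keratin KRT16 was at 2.85 and 0.239 FPKM, the muscle intermediate filament gene DES at 1.97 and 0.0780 FPKM, and the linker histone HIST1H1B at 2.92 and 0.388 FPKM.

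Among the same kind of loci, the highest ratios were those of REXO1 (chromosome 19, 1815245 to 1848452), at 11.1 FPKM in the control and 183 FPKM after silencing, and of HEATR6 (chromosome 17, 58118725 to 58156419), at 6.42 and 75.1 FPKM. Their log2 ratios were 3.98 and 3.45. PDK4, which inhibits pyruvate dehydrogenase, was at 0.516 and 4.59 FPKM (log2 ratio 2.32). HLA-B at its main locus (chromosome 6, 31321649 to 31324989) was at 8.68 and 43.8 FPKM (log2 ratio 2.27). Reads shared with its copies on alternate haplotype contigs make this ratio uncertain. The copy with the highest FPKM was at 28.2 and 75.2 FPKM (log2 ratio 1.40). The joint locus of RTEL1 and TNFRSF6B, a helicase gene and a decoy receptor gene that the table does not separate, was at 105 and 470 FPKM (log2 ratio 2.15). Stress-induced genes followed, with NUPR1 at 5.74 and 26.2 FPKM, GDF15 at 19.4 and 72.4 FPKM, and haem oxygenase HMOX1 at 21.1 and 73.4 FPKM. The sterol transporter ABCG1 was at 0.892 and 4.71 FPKM, and the potassium channel gene KCNJ4 at 0.311 and 2.38 FPKM.

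The listed genes of DNA replication were lower. Of the 26 members of the S phase list, 12 were listed, and all 12 were lower (11 after centring), with a median log2 ratio of -0.95. POLE2, a subunit of DNA polymerase epsilon, was at 10.9 and 4.18 FPKM. The replicative helicase subunit MCM4 was at 72.6 and 32.5 FPKM, the methylation maintenance factor UHRF1 at 38.2 and 17.6 FPKM, and the origin licensing factor CDC6 at 25.2 and 11.7 FPKM. The list's median lay at percentile 1.16 of random lists of listed loci matched on level, and at percentile 10.7 when matched on transcript GC content. Of 25 mitotic genes, 6 were listed and all 6 were lower (4 after centring), including the kinase CDK1 (log2 ratio -0.96), the motor KIF11 (-0.91), HMMR (-0.82) and the ubiquitin-conjugating enzyme UBE2C (-0.82). The median of the mitotic list, -0.82, lay at percentile 36.6 of the random lists. Among G1 cyclins, CDKs and CDK inhibitors, 4 of 16 were listed and lower, with a median of -1.39 at percentile 0.88. These were CDK6 (log2 ratio -1.87) and CDK2 (-0.87), which promote G1 progression, and CDKN1A (-1.65) and RBL1 (-1.13), which restrain it.

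The listed glycolytic genes were lower. All 7 listed members of 24 were lower (6 after centring), with a median log2 ratio of -1.29 at percentile 0.155. Besides LDHA they included PFKFB4 (log2 ratio -1.51), aldolase ALDOC (-1.35) and the pyruvate dehydrogenase kinase PDK1 (-1.29). Of 19 hypoxia-responsive genes, 5 were listed and all were lower (median -1.02, percentile 5.46), among them adrenomedullin ADM (-1.61), PDK1, the glucose transporter SLC2A1 (-1.02) and the mitophagy receptor BNIP3L (-0.93). SLC2A1 and PDK1 belong to both lists. Of 20 genes of the angiogenic factor list, 6 were listed, 4 lower and 2 higher (median -1.01, percentile 13.5). That list mixes growth factors, receptors and semaphorins, so its median has no single functional direction. The semaphorins SEMA3C (-1.89) and SEMA3A (-1.14) and the receptor NRP1 (-1.18) were lower, and the joint locus of FIGF and PIR (0.99) and PDGFB (0.96) were higher.

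The listed endoplasmic reticulum chaperone genes were higher. All 5 listed members of 17 were higher, with a median log2 ratio of 0.93 at percentile 96.8, including the chaperone HSPA5 (log2 ratio 1.16), CRELD2 (1.15), HERPUD1 (0.93) and the secreted factor MANF (0.78). Of 20 genes of the ATF4 and amino acid response, 4 were higher and 1 lower (median 0.90, percentile 92.2). NUPR1 (2.10), the serine synthesis enzyme PHGDH (1.33) and asparagine synthetase ASNS (0.90) were higher, and SESN2 (-1.21) was lower. Of 14 cytosolic heat-shock proteins, by contrast, the 3 listed were lower, DNAJA1 (-0.80), HSPH1 (-0.80) and BAG3 (-0.77, but 0.032 after centring).

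Class I HLA genes formed the antigen presentation result. The list's 4 listed genes occupied 8 loci, 7 of which were higher, with a median log2 ratio of 1.15 at percentile 98.8. HLA-B was higher at all 4 of its loci (log2 ratios 2.27, 1.40, 1.25 and 1.11), while HLA-F on an alternate haplotype contig was at 2.67 FPKM in the control and listed at 0 after silencing. HLA-G, a class I gene outside the fixed list, has the same locus span on that contig, and was at 0.534 FPKM in the control and listed at 0 after silencing. Only the HLA-B locus on the main chromosome lies outside alternate haplotype contigs, so these loci are not independent. Of 20 p53 target genes, 8 were listed, 6 lower and 2 higher, with a median of -1.08 at percentile 1.01. CDKN1A (-1.65), GADD45A (-1.39) and SESN2 (-1.21) were lower, and GDF15 (1.87) was higher. Immediate-early genes were split, with 3 of the 6 listed higher and 3 lower (median -0.04, or 0.76 after centring, percentile 57.1), FOSL1 (-1.31) and ATF3 (-1.30) against EGR3 (1.13) and JUND (1.10). The 4 listed genes of the stem-cell list were split as well (median -0.07, or 0.73 after centring, percentile 39.6), with ALDH1A1 (-1.68) and KLF4 (-0.93) lower and MSI1 (0.89) and ALDH1A3 (0.80) higher.

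**Figure D2:**
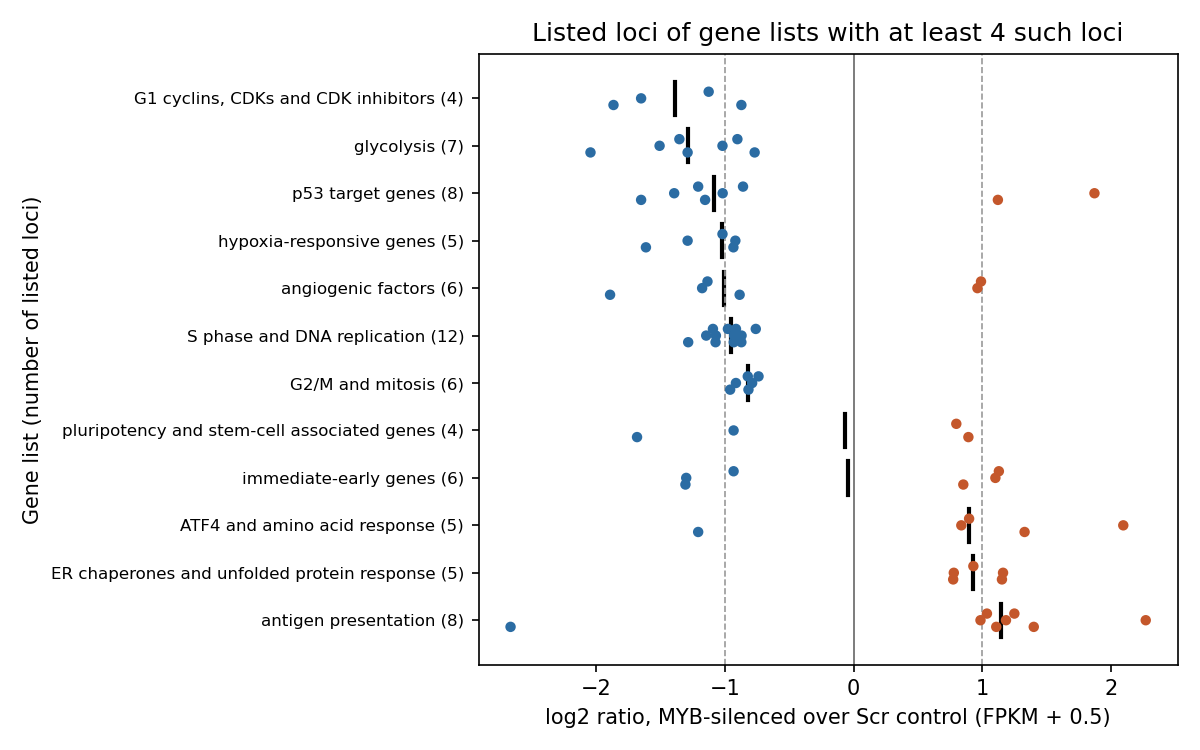
log2 ratio (MYB-silenced over Scr control, FPKM + 0.5) of each listed locus, horizontal axis, in the 12 gene lists with at least 4 loci that passed the level filter; points are loci, black bars list medians and dashed lines 2-fold differences. The S phase, mitotic, G1, glycolysis and hypoxia lists hold only lower loci (11 of 12, 4 of 6, 4 of 4, 6 of 7 and 5 of 5 after centring). The endoplasmic reticulum chaperone list holds only higher ones. The leftmost antigen presentation point, HLA-F, is listed at 0 after silencing.

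Lists with 1 to 3 loci above the level filter numbered 27 and were described by their members. Of 23 reported MYB targets, 3 were listed. BIRC3 (log2 ratio -2.28) and the hedgehog ligand gene SHH (15.6 and 6.24 FPKM, -1.25) were lower, and HSPA5 (1.16) was higher. In the hedgehog list of 14, the receptor gene PTCH1 was listed beside SHH but was higher (1.06 and 2.13 FPKM, 0.75). BIRC3 was the only listed member of the list of 10 anti-apoptotic BCL2 family and IAP genes. BIRC7, an IAP gene outside that list, was higher (2.35 and 7.62 FPKM, 1.51). Of the pro-apoptotic genes, BBC3 (1.12) and BMF (0.86) were higher and BNIP3L (-0.93) lower. Among cytokines and NF-kB targets, CXCL2 (-1.89) and CXCL5 (-1.02) were lower, as was TNFAIP3 below the level filter (1.58 and 0.307 FPKM). The interferon-stimulated genes OASL (-1.18), IFIT3 (-1.12) and IFIT1 (-1.04) were lower, and so was OAS2 below the filter (0.486 and 0.0630 FPKM).

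Of the receptor tyrosine kinases, EGFR (21.9 and 9.89 FPKM, log2 ratio -1.11) and the collagen receptor DDR2 (-1.04) were lower. Wnt list members DKK1 (-2.13) and TCF7 (-0.96) were lower. Notch list members HES4 (1.07) and DLL1 (0.96) were higher and MAML2 (-0.71, but 0.088 after centring) was lower. PMEPA1 (-1.09) for the TGF-beta list, AMOTL2 (-0.81) and, below the filter, ANKRD1 (1.03 and 0.163 FPKM) for the YAP/TEAD list, and FOSL1 for the MAPK feedback list were lower. Of 35 extracellular matrix genes, 3 were listed, COL6A2 (1.26), AGRN (0.95) and COL4A2 (0.73), and of 19 integrins 2 were listed, ITGB4 (0.85) and ITGA5 (0.75), all higher. Of the proteases, MMP14 (1.41) and CTSL1 (0.89) were higher and urokinase PLAU (-0.74, but 0.065 after centring) was lower. The cholesterol genes INSIG1 (0.79) and MVD (0.78), HMOX1 for the NRF2 list and the ribosomal protein RPS21 (0.98) were higher. The ribosome biogenesis factors NOP58 (-1.16) and WDR43 (-0.78, but 0.022 after centring) and the histone HIST1H1E (-1.60) were lower. ANXA10 (-1.27) and ANXA1 (-1.03) were lower and S100A6 (0.93) higher. TUBB3 (1.05) was higher and TPM1 (-0.84) lower. The reference gene list had TFRC (-0.98) and PGK1 (-0.90) listed, both lower. DES stood for the fibroblast list, and the joint IGF2 and INS locus (0.83) for the endocrine list. The mucin list had MSLN alone, below the filter (0.131 and 0.781 FPKM). HLA-G, BIRC7, PDGFB, OAS2, TNFAIP3, ANKRD1 and MSLN were named after their values were seen. No locus was listed for 10 lists: epithelial markers, mesenchymal markers, fatty acid synthesis, nuclear oxidative phosphorylation, mitochondrially encoded genes, linker and variant histones (a list without HIST1H1B and HIST1H1E, both lower), pancreas regulators, and blood, endothelial and acinar markers.

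Loci at 0 in either library numbered 35, and 25 of them were small nucleolar RNA genes. Of 30 listed loci named SNOR, 15 were at 0 in the Scr control library, 10 at 0 in the MYB-silenced library and 5 above 0 in both. Among SNOR loci at 0 in the other library, the highest in the control were SNORD63 (275 FPKM) and SNORA27 (12.4 FPKM). After silencing they were SNORD37 (944 FPKM), SNORD4B (320 FPKM) and SNORD59A (299 FPKM). These records cover long spans, such as 3976054 to 3985461 on chromosome 19 for SNORD37 and 137890571 to 137911318 on chromosome 5 for SNORD63. How reads were assigned within them is not given in the sources used here, so these values are uncertain. The other 10 loci at 0 were all at 0 in the MYB-silenced library. They included the growth hormone gene GH1 (chromosome 17, 61994038 to 61996198), listed at 2 records with 42.9 and 4.53 FPKM in the control.

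Direction moved with transcript GC content. The median GC content was 44.5% for lower loci and 60.6% for higher loci, and the share of lower loci was 92.7% in the lowest of 5 GC content bins and 10.7% in the highest. Beside this trend, the S phase loci had a median GC content of 48.3%, the mitotic loci 38.2%, the glycolytic loci 51.2%, the endoplasmic reticulum chaperone loci 50.2%, the antigen presentation loci 59.5% and the p53 target loci 59.4%. With random lists matched on GC content, the medians of the glycolysis, G1 and p53 lists lay at percentiles 0.73, 0.77 and 0.56. That of the antigen presentation list lay at 99.4, but its 8 loci belong to 4 genes and are not independent, so its percentiles overstate how unusual it is. Matched on GC content, the medians of the other lists lay less far out than those of the glycolysis, G1, p53 and antigen presentation lists. They were at 10.7 for S phase, 77.5 for mitosis, 11.1 for hypoxia, 12.7 for angiogenic factors and 18.6 for immediate-early genes. The ATF4 list lay at 74.8, the chaperones at 92.9 and the stem-cell list at 56.0. The share of lower mitotic loci lay at percentile 95.9 matched on level and 86.6 matched on GC content. The p-values in the authors' deposited table were unadjusted, with 253 up to 0.01 and a near-constant 142, 139 and 146 in the last 3 steps of 0.01.

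**Figure D3:**
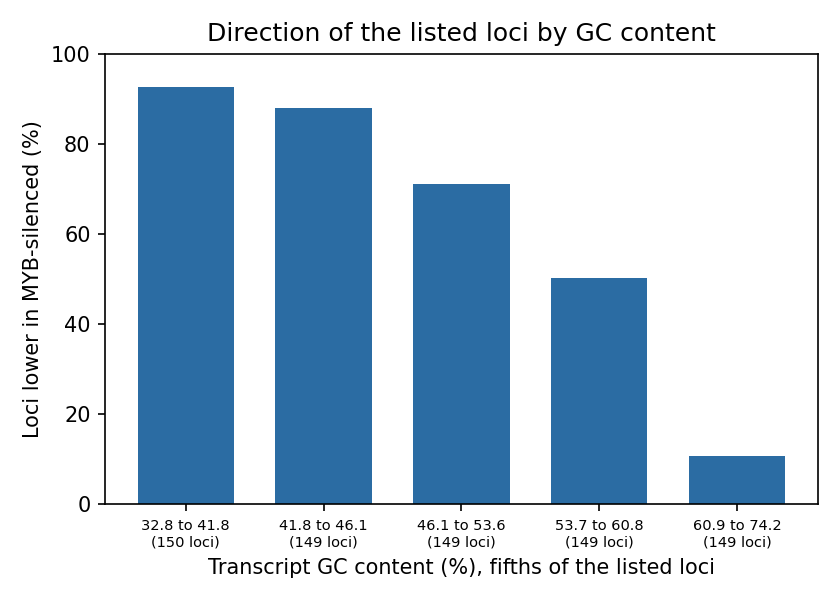
Share of loci lower in the MYB-silenced library (vertical axis, percent) in 5 bins of transcript GC content with about equal numbers of loci (horizontal axis, percent), for listed loci with a mean of at least 1 FPKM and a GC value; bars are shares without an error because each group has 1 library. The share is 92.7% in the lowest bin and 10.7% in the highest.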

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

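MYB was lower under every setting run, with log2 ratios of -9.86 as reported, -9.30 with a pseudocount of 1, -10.55 with 0.1 and -9.06 when centred. The 197 lower and 159 higher loci became 497 and 300 at 1.5-fold, and 48 and 35 at 3-fold. Centring on the median ratio (-0.80) gave 31 and 300, by construction, since a median over genes selected for change is no estimate of unchanged genes. The counts stayed within 1.5-fold for both other pseudocounts, no level filter, a mean of at least 5 FPKM, and the sets without loci at 0 and small RNA genes (181 and 142) or without extra contigs (195 and 154). The authors' 516 lower and 320 higher calls fell to 166 and 87 at a p-value up to 0.01, and to 197 and 159 with the 2-fold and level rules. Only centring reversed the sign of a named locus or list median. It did so for BAG3 (0.0321), LIPA (0.0321), MAML2 (0.088), PLAU (0.065) and WDR43 (0.022), and for the medians of the immediate-early (0.76) and stem-cell (0.73) lists. The 12 list medians kept their sign and moved by less than 1.5-fold under the other settings that could be computed. Among 142 loci other than MYB, 24 moved by over 1.5-fold with a pseudocount of 0.1 and 12 with a pseudocount of 1, while centring shifts every locus by the same amount, over 1.5-fold. Scaling to a common sum and quantile normalization were not run on a table of selected genes. The sets without loci at 0 or extra contigs were chosen after seeing the data. No library could be left out, and depth is unknown, so values under 1 FPKM are the least certain.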

Other observations

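Only the GC content and transcript length tests of the S phase list had their criteria written before their results were seen. The tests of chance selection, of the chaperone list, of the GC trend, of MYB with GH1 and of the muscle transcripts, the 5 gene lists and 3 name families used here and the genes named from them were chosen after the values were seen.

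Further gene groups were described among the listed loci. Of 42 proteins of homologous recombination and the Fanconi anaemia pathway, 13 were listed and all 13 were lower after silencing (12 after centring), with a median log2 ratio of -0.99. They included the repair gene XRCC2 (7.54 and 2.62 FPKM), the polymerase POLQ (6.31 and 2.06 FPKM), the nuclease EXO1 (12.7 and 5.31 FPKM) and BRCA2 (4.49 and 2.04 FPKM). Of 73 splicing factors, 26 were listed and all 26 were lower (median -0.84; 16 lower and 9 higher after centring), among them TRA2B (90.1 and 33.7 FPKM), SFPQ (169 and 72.8 FPKM) and SRSF3 (184 and 91.7 FPKM). The repair loci had a median GC content of 41.2%, and their share of lower loci lay at percentile 99.96 of random lists matched on level but at 88.5 matched on GC content, so all 13 lower was not unusual for loci of that GC content. The splicing loci had a median GC content of 44.4%, and matched on GC content their share lay at percentile 99.8 and their median at 67.6.

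Of 46 lysosomal proteins, 12 were listed, 10 higher and 2 lower (median 0.91; 11 and 1 after centring), with the hydrolases IDUA (1.79 and 4.63 FPKM), MAN2B1 (11.5 and 24.8 FPKM), SMPD1 (8.59 and 18.1 FPKM) and NAGLU (6.46 and 13.5 FPKM) higher and CTSC and LIPA (239 and 140 FPKM, but higher after centring) lower. The lysosomal loci had a median GC content of 62.4%. Their share of lower loci lay at percentile 0.025 and their median at 99.2 matched on level, but at 6.19 and 77.2 matched on GC content, inside the range of other loci of that GC content. All 3 listed HOX loci lie in the HOXB cluster and were higher, with HOXB9 at 34.3 and 95.3 FPKM and HOXB8 at 46.3 and 97.7 FPKM. All 6 loci named HIST were lower, with HIST1H4D and HIST1H4L listed at 0 after silencing and HIST1H4L below the level filter. Of 7 loci named KIF, 5 were lower and 2 higher.

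MYB at 981 FPKM, the highest value among the listed loci in the Scr control library, occurred together with GH1 at 42.9 FPKM. After silencing MYB was at 0.554 FPKM and GH1 was listed at 0. GH1 was the only listed member of a list of 15 pituitary markers. GH1 was 1.97 times as high in the control as the highest listed muscle locus, TRIM55 (21.8 and 10.8 FPKM). TRIM55 remained present after silencing, so it does not trace muscle RNA confined to the control, and this ratio cannot decide on striated muscle as a source. Of the muscle loci under 1 FPKM after silencing, the highest in the control was MB at 3.05 FPKM. A candidate explanation is MYB transcribed from an introduced plasmid, since some mammalian expression plasmids carry a growth hormone polyadenylation signal and the label of this library reads as MYB overexpression. Such a plasmid and a dependence of GH1 on MYB in the cells cannot be told apart, because both allow GH1 at 42.88 FPKM in 1 library and at 0 in the other, and read positions were not analysed here.

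Of 40 striated muscle markers, 10 were listed and all 10 were lower, and 8 of these were under 1 FPKM in the MYB-silenced library. HSPB7, MYH7, MYL3 and TNNT2 were below the level filter, which 6 of the 10 passed. The 8 loci were weakly expressed in the control too, from 0.491 FPKM for HSPB7 to 3.05 FPKM for MB, with TNNC1 at 2.09, MYH7 at 1.84 and MYL3 at 1.05 FPKM, and DES among them is also on the fibroblast list. TRIM55 (21.8 and 10.8 FPKM) and MYPN (5.24 and 1.90 FPKM) were above 1 FPKM in both libraries. RNA from muscle or heart in the Scr control library and MYB-dependent expression in the cells cannot be told apart for these loci, because each group has 1 library and both explanations predict the same 8 loci near 0.

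The trend of direction with GC content spanned 81.9 percentage points between the lowest and the highest of 5 bins. GC content bias between the libraries may produce such a trend, and for the listed loci as a whole it cannot be told apart from a difference between the cells, because each group has 1 library. For the S phase list, the share of lower members lay at percentile 99.45 of random lists matched on GC content, but its median lay at 10.7. The share lay at percentile 99.86 matched on transcript length and at 99.7 matched on level. That share was thus unusual among listed loci of similar GC content, length or level. GC content bias, transcript length and chance selection by unadjusted p-values all stay open for that list. These percentiles cannot decide between them, since each group has 1 library. In addition, 12 fixed lists and others added after the values were seen were looked at. For the endoplasmic reticulum chaperones, all higher, the share of lower members lay at percentile 0.09 of GC-matched lists. Their median lay at 92.9. This test was chosen after all these loci were seen to be higher, so it cannot decide on GC content there.

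The flat part of the deposited p-values, extended over 0 to 0.05, comes to 712 of the 836 loci and leaves 124 above it. In that flat part, at p-values from 0.02 to 0.05, 259 loci were lower and 168 higher, so it was not balanced in direction. If chance p-values were evenly spread, a test of 16720 genes would give 836 under 0.05. Whether p-values made without replicates spread evenly by chance was not tested, and the number tested is not given in the sources used here. The flat part therefore cannot be read as a count of chance loci.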
